A study of Mus musculus with 6 samples.

How the data were processed

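Whole corneas of mice with benzalkonium chloride-induced dry eye were collected after 10 days of vehicle or luteolin treatment and flash frozen, and RNA was extracted with Trizol and made into Illumina TruSeq libraries, per the labels' protocols. The 6 libraries were grouped by their titles, 3 vehicle and 3 luteolin. The submitters' processing notes name Bowtie2 2.2.5, RSEM 1.2.12 and the mouse build mm9. The role of each tool, the annotation and the use of strand in counting are not given in the sources used here, so reads of a gene and of an antisense or overlapping partner may not be told apart. No coordinates are given, because the reference at hand was of another build than mm9.

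The authors deposited 4 measures per library for 17794 genes. The estimated counts, per the file headers read counts, were not whole in 10.3% to 10.8% of the values (more than 0.001 from a whole number), as when reads are divided between similar genes. The deposited normalized read counts are a signal in which the counts were divided by 1 factor per library, between 0.945 and 1.07. The deposited FPKM values, per the file headers, are fragments scaled by gene length and library depth. The deposited TPM values, per the file headers, are scaled to a common total in each library. Every per-sample column of the table was mapped to a sample by its name, and 8 columns of group averages were not used. The table lists only genes with reads in at least 1 library.

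The estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 13838 and removed 3956, libraries were scaled by TMM, and the quasi-likelihood test compared luteolin with vehicle without a replicate block. P-values were adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. A log2 fold change is luteolin minus vehicle, and its SE is the change divided by the square root of the quasi-likelihood F. CPM values are counts scaled to library size with the TMM factors. The common biological coefficient of variation was 13.8%. Where the luteolin group had 0 counts a bound was computed against 3 counts over the group (0.0646 CPM), and with 1 to 3 counts an exact conditional 95% interval was given. Medians of lists that hold genes with 0 counts were the same with those genes at their bound.

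Before the data were examined, 36 gene lists were fixed: cell types of the cornea and neighbouring tissue, processes relevant to dry eye and to a flavone, and signs of sample handling. No gene was in more than 1 list. The 33 lists with at least 3 tested members were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists: 15 passed, 3 upward and 12 downward, and 0 passed with a correlation estimated from the data, where adjusted p ran upward from 0.410. Members were also counted after adjustment over the list alone, and that count is given where it differed. The self-contained test fry was run beside camera. It asks whether the genes of a list move, on balance, one way (21 lists) or change in either direction (29 lists), and compares no list with other genes.

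The genes named were set by a rule fixed with the lists: the 10 higher and 10 lower genes with the largest absolute log2 fold change among those with adjusted p under 0.05, a mean of at least 5 CPM and groups that did not overlap, passing over model names; and from each list the 2 tested members with the smallest p, or 4 where over 3 passed. Values of some genes that this rule chose are not reported here. Other list members that are named, such as Krt12, Krt5, Krt6b, Muc4, Cldn1, Col3a1, Lyz2, Ogn, Txnip, Idi1, Mvd, Cry1, Dbp, Ciart, Per2 and the members that did not pass, were chosen after their values were seen, as were the genes drawn in the plot of CPM per library.

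Alternatives fixed beforehand were DESeq2 1.42.0, other normalization factors (relative log expression, upper quartile, library sizes only), no filter, a filter of 1 CPM in 3 libraries, robust dispersion, the replicate number as a block, limma-trend on log2 FPKM with a pseudocount of 1 or 0.1, and leaving out each library. A per-library loess correction for gene length, with the length implied by count and FPKM for 97.0% of tested genes, and the mean of the skeletal muscle list as a covariate were added after seeing the data. The code was tested on simulated data for the comparison of luteolin with vehicle, with 200 of 13838 genes changed, 50 per fold: it recovered 52% at 1.5-fold, 72% at 2-fold, 92% at 4-fold and 94% at 8-fold, with 7.19% of the calls false, and made 0 calls with no change simulated. The simulated changes were evenly up and down and far fewer than the 8157 genes called in the data, so these rates may not hold there. Counts had decimals in all 6 libraries also for Hspa1b, Hspa5, Dbp and Rpl3, whose values are uncertain where reads were divided between similar genes. Figures were drawn with matplotlib 3.10.9.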

Results

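Gene expression was measured by RNA sequencing in whole corneas of mice with experimental dry eye, induced with benzalkonium chloride, a detergent preservative that damages the ocular surface. The animals were then treated for 10 days with vehicle or with luteolin, a plant flavone, and the series holds 3 libraries of each group. Undamaged corneas were not analysed here, so every value below compares treated with vehicle-treated damaged tissue. Library totals ran from 16084855 to 16469699 estimated counts. Pearson correlations of log2 CPM across genes, which are not independent replicates, were 0.971 to 0.991 within groups and 0.901 to 0.919 between groups. The first principal component held 81.1% of the variance and separated the groups, and the second held 8.20% and set vehicle 2 (-32.6) apart from vehicle 3 (34.3). Counts of every pair of libraries within a group differed by more than sampling noise (chi-square per degree of freedom 6.61 to 31.8). The labels do not say whether the libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical.

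The comparison asked how the corneal transcriptome of mice with dry eye differed after luteolin. Luteolin-treated corneas had lower transcript levels of chemokines, leukocyte and vessel markers, matrix metalloproteinases, myofibroblast genes and mitotic genes, and higher levels of most corneal epithelial and junction genes. All 12 tested markers of macrophages and dendritic cells fell, as did 12 of 15 cytokine and chemokine genes and 10 of 11 fibrosis genes, while 10 of 12 corneal epithelial genes rose. Of 13838 genes tested with edgeR's quasi-likelihood test, 8157 had a Benjamini-Hochberg adjusted p under 0.05, 3949 of them higher and 4208 lower with luteolin. Large decreases outnumbered large increases: 2087 genes were lower and 638 higher by over 1 on the log2 scale, and 954 were lower and 122 higher by over 2. A further 2999 of the called genes differed by less than 0.5. The libraries of both groups did not overlap for 67.4% of the tested genes, where chance gives 10%. The share of called genes that were lower was 51.6% with TMM factors and 63.6% with library sizes only, which moved the median log2 fold change of all tested genes from -0.02 to -0.13; upper quartile factors gave 61.9% and -0.11, and limma-trend on log2(FPKM + 1) gave 65.1%.

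**Figure D1:**
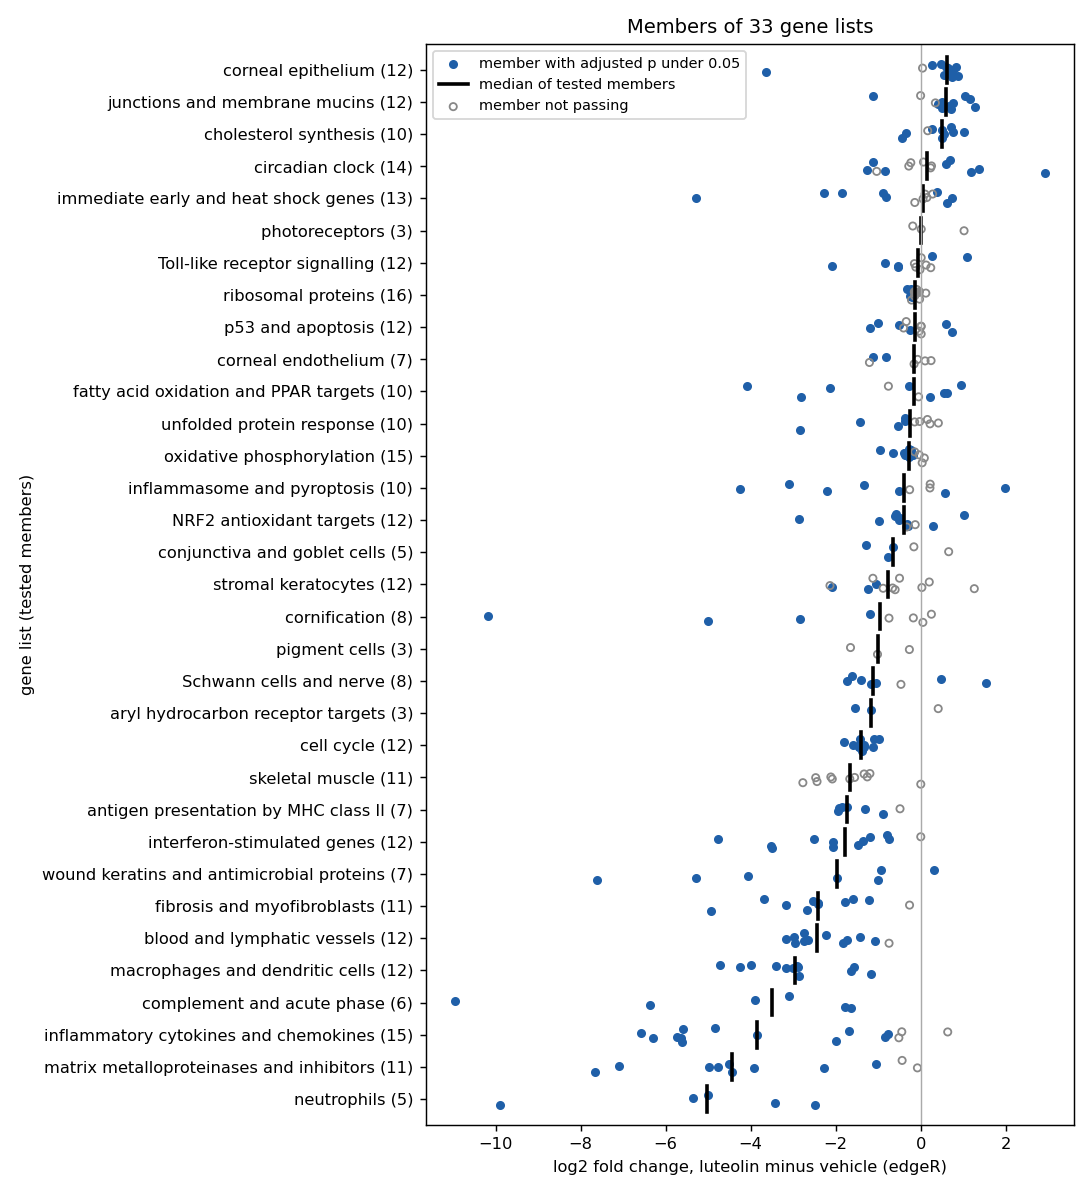
Log2 fold changes (luteolin minus vehicle, edgeR) of the tested members of 33 gene lists, 1 point per gene, filled where the adjusted p was under 0.05, with a black bar at each list's median and the number of tested members in brackets. The neutrophil list had the lowest median (-5.01) and the corneal epithelium list the highest (0.61); fitted values near -10 belong to genes with 0 to 3 luteolin counts.

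By the naming rule, which asks for a mean of at least 5 CPM, the 10 largest decreases included acute phase, chemokine and wound keratin genes. Saa3 (gene ID 20210), an acute phase serum amyloid, stood at 143 ± 96.1 CPM (SD, n = 3) with vehicle and had 3 counts over the luteolin group, a ratio of 2213 with a 95% exact counting interval of 757 to 10740 (without vehicle 2 a ratio of 1354, interval 463 to 6571). Ccl7 (gene ID 20306), a monocyte chemokine, had 2 luteolin counts and a ratio of 398 with an interval of 110 to 3288. Cxcl3 (gene ID 330122), a neutrophil chemokine, had 0 luteolin counts and was at least 179-fold lower against a floor of 3 counts over the group, with vehicle levels of 4.50, 4.33 and 25.9 CPM (at least 69.2-fold without vehicle 3 and at least 119-fold without luteolin 3). These intervals and floors cover counting error only. Ppbp, a platelet and neutrophil chemokine, was 201-fold lower (313-fold without luteolin 1), Csn3, the gene of kappa-casein, 198-fold, and Il1b, the interleukin-1 beta gene, 95.7-fold. Krt16 (gene ID 16666), a keratin of wounded epithelium, went from 581 ± 214 to 2.97 ± 2.11 CPM (SD, n = 3), 195-fold lower or 327-fold without luteolin 3. Its counts had decimals in 3 libraries, so part of its reads may belong to similar genes. Timp1 (gene ID 21857), a secreted inhibitor of metalloproteinases, went from 50.9 ± 7.27 to 0.366 ± 0.0380 CPM (SD, n = 3). Chil1, a chitinase-like secreted protein, was 105-fold lower (SE of the log2 fold change 0.787, 59.6-fold without vehicle 2 and 185-fold without luteolin 2) and Dmkn, dermokine, 98.6-fold (SE 0.883). The edgeR adjusted p of these genes ran from 1.52e-05 for Timp1 to 0.00618 for Cxcl3.

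The 10 largest increases by the same rule were smaller and included 3 cytochrome P450 genes. Upk3b (gene ID 100647), a uroplakin, rose from 0.783 ± 0.238 to 20.7 ± 2.44 CPM (SD, n = 3), a log2 fold change of 4.71 (SE 0.217, edgeR adjusted p = 3.01e-05). Pdyn (gene ID 18610), which encodes the precursor of the dynorphin opioid peptides, was 16.2-fold higher, and Cyp2b19, an epidermal P450, 12.8-fold (19.6-fold without vehicle 2). Pygl (gene ID 110095), the liver form of glycogen phosphorylase, had the highest level of the 10 and rose from 33.9 ± 10.3 to 271 ± 30.1 CPM (SD, n = 3). Ano4, Adamts18, Cyp4f15 and Msln, the mesothelin gene, were between 8.15-fold and 10.5-fold higher. Necab1 (log2 fold change 4.46, without vehicle 2 5.24) and the fatty acid hydroxylase Cyp4a12a (4.17) had counts with decimals in all 6 libraries, so part of their reads was divided with another gene, for Cyp4a12a a near-identical paralog being known, and their values are uncertain. The naming rule required that the libraries of each gene did not overlap between groups.

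Inflammatory signals fell in several of the lists fixed beforehand. Of 15 tested cytokine and chemokine genes, 12 fell, 0 rose and 3 did not pass, with a median log2 fold change of -3.86 (camera adjusted p = 0.000251, and adjusted p = 0.604 with an estimated correlation). Ccl2, a monocyte chemokine, was 78.1-fold lower, the neutrophil chemokine Cxcl5 28.5-fold and Ptgs2, the inducible cyclooxygenase, 14.5-fold. The 3 that did not pass were Il1a (-0.51), Tnf (0.64) and Nfkbia (-0.44), which passed without vehicle 1 (-0.64). All 6 tested complement and acute phase genes fell (median -3.50, camera adjusted p = 0.000543, and adjusted p = 0.587 with an estimated correlation): Cfb, complement factor B, was 14.9-fold lower, and Hp, haptoglobin, had 1 luteolin count (ratio 112, interval 19.7 to 4460, and at least 25.2-fold lower with 0 counts without luteolin 2). Of 12 interferon-stimulated genes 11 fell (median -1.77, camera adjusted p = 0.000312, and adjusted p = 0.604 with an estimated correlation), among them Ifi44 (log2 fold change -3.49, SE 0.237), Ifit1 (-2.07) and Oas1a (-2.07). Oas1a and Ifit1 belong to families of similar genes and had counts with decimals. Of 7 genes of antigen presentation by MHC class II, 6 fell, or 7 adjusted over the list alone (median -1.72, camera adjusted p = 0.00734, and adjusted p = 0.639 with an estimated correlation), with H2-Aa 3.88-fold, H2-Ab1 3.77-fold, H2-Eb1 3.63-fold and the invariant chain gene Cd74 3.30-fold lower.

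Genes of the inflammasome and of Toll-like receptor signalling went both ways. In the inflammasome list 5 of 10 fell and 2 rose (camera adjusted p = 0.491): the sensors Nlrp3 (log2 fold change -4.24, without vehicle 3 -3.36) and Aim2 (-3.09) and the adaptor Pycard (-0.51) fell, while the sensor Nlrp1b rose from 0.901 to 3.57 CPM and Txnip by 0.56 on the log2 scale. The call of Txnip ended without any 1 luteolin library (0.50 to 0.59), which left 1 higher member, and its value was 0.34 without vehicle 1. In the Toll-like receptor list 4 of 12 fell and 2 rose (camera adjusted p = 0.760). Tlr5, the flagellin receptor, was 2.13-fold higher, Lbp, which carries bacterial lipopolysaccharide, 4.25-fold lower, and Hmgb1 1.44-fold lower. Traf6 rose by 0.27 on the log2 scale, a call that ended after a correction for gene length (log2 fold change 0.15, edgeR adjusted p = 0.0563, over the alternatives 0.00496 to 0.0563).

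Markers of leukocytes and vessels fell together. All 12 tested macrophage and dendritic cell markers fell (median -2.96, camera adjusted p = 6.75e-05, and adjusted p = 0.598 with an estimated correlation). The mannose receptor gene Mrc1 (gene ID 17533) went from 31.4 ± 4.15 to 2.97 ± 0.359 CPM (SD, n = 3), a log2 fold change of -3.40 (SE 0.148, edgeR adjusted p = 2.79e-05), C1qb and C1qc, which encode chains of complement C1q, were 9.06-fold and 8.04-fold lower, and the Fc receptor gene Fcgr1 26.6-fold (40.8-fold without luteolin 2). All 5 tested neutrophil markers fell (median -5.01, camera adjusted p = 0.00345, and adjusted p = 0.495 with an estimated correlation). Csf3r, the receptor of granulocyte colony-stimulating factor, was 40.8-fold lower, the chemokine receptor Cxcr2 32.3-fold, S100a9 10.8-fold (22.8-fold without luteolin 3), and S100a8 had 0 luteolin counts and was at least 114-fold lower (at least 76.6-fold without vehicle 3 and 76.1-fold without luteolin 3). Only 2 of 12 lymphocyte markers, Cd4 and Lck, had enough reads to test; both fell (log2 fold changes -3.17 and -1.88), Cd4 had 3 luteolin counts without luteolin 3 (ratio 20.6, interval 6.87 to 102), and without vehicle 3, 4 of 5 tested were lower. Of 12 markers of blood and lymphatic vessels 11 fell and Kdr (-0.74, without vehicle 3 -0.94 and passing) did not pass (median -2.44, camera adjusted p = 0.000137, and adjusted p = 0.604 with an estimated correlation). The endothelial cadherin Cdh5 (gene ID 12562) went from 24.0 ± 6.04 to 2.65 ± 0.753 CPM (SD, n = 3), and Plvap, Esam and Vwf were 7.87-fold, 7.79-fold and 6.71-fold lower. The conjunctival keratins Krt4, Krt13 and Krt19 were lower in the same libraries (log2 fold changes -1.28, -0.78 and -0.66), with groups that did not overlap. The other 2 tested genes of the conjunctiva list did not pass.

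Libraries also differed in tissue content in a way that did not follow the groups. The mean log2 CPM of 11 skeletal muscle genes was 3.42, 4.17 and -1.54 in vehicle 1, 2 and 3 and -0.59, -0.92 and 2.96 in luteolin 1, 2 and 3. That of the keratocyte list was 7.21, 8.17 and 6.62 with vehicle and 6.95, 7.18 and 6.02 with luteolin. Ckm, the muscle creatine kinase gene, stood at 7.82 ± 7.73 CPM with vehicle and 1.14 ± 1.86 CPM with luteolin (SD, n = 3), and Myh1, a fast myosin heavy chain gene, at 16.2 ± 15.2 and 2.92 ± 3.94 CPM (SD, n = 3), and 0 of the 11 muscle genes passed (median -1.67, camera adjusted p = 0.491). Without vehicle 3, 5 of 12 muscle genes were lower, Ckm (log2 fold change -3.37) and Myh1 (-3.07) among them, and the list had a camera adjusted p of 0.0138 (over the alternatives 0.0138 to 0.949). Without luteolin 3 the median was -5.09 and 1 of 12 passed, and without vehicle 2 the median was -0.70.

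**Figure D2:**
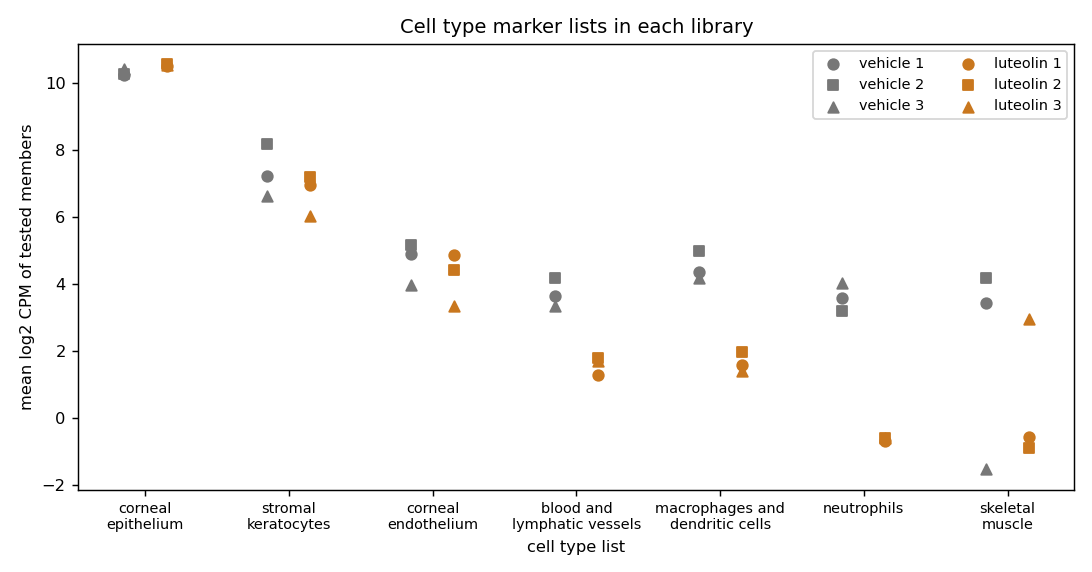
Mean log2 CPM of the tested members of 7 cell type lists in each library, grey for vehicle and orange for luteolin, with the marker shape giving the replicate number. The macrophage list lay between 4.17 and 4.99 with vehicle and between 1.41 and 1.96 with luteolin, whereas the skeletal muscle list was near 3 to 4 in vehicle 1, vehicle 2 and luteolin 3 and below 0 in the other libraries.

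Genes of matrix breakdown and fibrosis fell. Of 11 matrix metalloproteinases and inhibitors 9 fell, and Mmp14 (-0.08) and Timp3 (-0.44) did not pass (median -4.43, camera adjusted p = 0.000251, and adjusted p = 0.410 with an estimated correlation). Mmp3, stromelysin 1, went from 767 ± 308 to 28.3 ± 15.8 CPM (SD, n = 3), and Mmp9, gelatinase B, and the macrophage elastase Mmp12 had log2 fold changes of -4.52 and -3.91. In the fibrosis and myofibroblast list 10 of 11 fell and Fn1 (-0.26, without vehicle 3 -0.37 and passing) did not pass (median -2.41, camera adjusted p = 7.09e-05, and adjusted p = 0.587 with an estimated correlation). Tnc, the matrix glycoprotein tenascin-C, was 30.6-fold lower, Postn, periostin, 5.79-fold, Acta2, smooth muscle actin, 5.32-fold and Tgfb1 2.34-fold.

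Keratocyte and corneal endothelial genes moved less. Of 12 keratocyte genes 3 were lower, or 1 adjusted over the list alone, and 9 did not pass (median -0.77, camera adjusted p = 0.236). The 3 were Cd34 (log2 fold change -2.08, SE 0.267), Ogn (-1.23) and the collagen gene Col1a2 (-1.04, edgeR adjusted p = 0.0384). The number of lower members was 1 without vehicle 1, vehicle 2, luteolin 1 or luteolin 3 and 6 without vehicle 3, and without vehicle 2 a further 2 were higher. The median was -0.43 without vehicle 2 and -0.50 without luteolin 3. With the replicate number as a block 8 members were lower and 1 higher, and the list passed (camera adjusted p = 0.0311, over the alternatives 0.0311 to 0.827). The call of Ogn ended without any 1 library except vehicle 3 (log2 fold changes -0.68 without vehicle 2 to -1.51 without luteolin 1). The call of Col1a2 ended without vehicle 1, vehicle 2, luteolin 1 or luteolin 3 (edgeR adjusted p 0.0729 to 0.0968, over the alternatives 0.000607 to 0.102). Of 7 corneal endothelium genes 2 fell, Tfap2b (log2 fold change -0.83) among them, and 5 did not pass (median -0.16, camera adjusted p = 0.491). The median was -0.84 without luteolin 1, -0.52 without vehicle 3, 0.03 without vehicle 2 and 0.25 without luteolin 3, and the number of lower members was 0 without vehicle 1, vehicle 2 or luteolin 3 and 1 without luteolin 2. The call of Tfap2b was lost without any 1 library except vehicle 3 (edgeR adjusted p 0.0509 to 0.0840).

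Most corneal epithelial genes rose, with Krt14 going the other way. Of 12 tested, 10 rose, 1 fell and 1 did not pass (median 0.61, camera adjusted p = 0.00734, and adjusted p = 0.604 with an estimated correlation). Krt12, the keratin of differentiated corneal epithelium, went from 14915 ± 2152 to 27197 ± 299 CPM (SD, n = 3). Pax6 (gene ID 18508), a transcription factor of the eye, was 1.67-fold higher, at 593 ± 24.7 and 989 ± 33.6 CPM (SD, n = 3), and Klf5 1.77-fold. Krt14 (gene ID 16664), a keratin of basal cells, went from 5209 ± 1753 to 418 ± 81.2 CPM (SD, n = 3), a log2 fold change of -3.64 (SE 0.292, edgeR adjusted p = 0.000114), while its usual partner Krt5 was 1.40-fold higher. Counts had decimals in 3 libraries for Krt14 and Krt5 and in 6 for Pax6, so part of their reads may belong to similar genes. Of 12 genes of junctions and membrane mucins 9 rose and 1, Cldn1, fell (median 0.59, camera adjusted p = 0.00344, and adjusted p = 0.604 with an estimated correlation). The membrane mucin Muc20 was 2.42-fold higher, the tight junction genes Ocln, F11r and Tjp1 2.25-fold, 1.70-fold and 1.63-fold.

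Genes of wounded epithelium and of dividing cells fell. Of 7 wound keratins and antimicrobial proteins 6 fell and Krt6b rose (median -1.97, camera adjusted p = 0.0131, and adjusted p = 0.587 with an estimated correlation). Krt17 was 16.7-fold lower (10.1-fold without vehicle 1), the protease inhibitor gene Slpi 3.92-fold and Krt6a 1.90-fold, and the near-identical Krt6a and Krt6b may share reads. Of 8 cornification genes 4 fell and 4 did not pass (median -0.96, camera adjusted p = 0.154). The cell envelope genes Sprr1a and Cnfn were 32.0-fold and 7.14-fold lower, Sprr1b had 0 luteolin counts and was at least 139-fold lower (at least 85.4-fold without vehicle 1), and Krt10 fell by 1.18 on the log2 scale, a call lost without luteolin 1 (edgeR adjusted p = 0.0548, over the alternatives 0.000263 to 0.0548). Without vehicle 2, 8 of 10 were lower, with a median of -2.34 and a camera adjusted p of 0.00358 (over the alternatives 0.00358 to 0.714), and the median was -0.56 without vehicle 1 and between -1.84 and -2.16 without a luteolin library. Of 5 conjunctival and goblet cell genes 3 fell (median -0.66, camera adjusted p = 0.236), among them Krt4 (log2 fold change -1.28) and Krt13 (-0.78), and without vehicle 2 a further 1 was higher. All 12 cell cycle genes fell (median -1.40, camera adjusted p = 0.000543, and adjusted p = 0.639 with an estimated correlation), with the replication genes Mcm5, Mcm2 and Pcna 3.50-fold, 2.68-fold and 1.97-fold and the mitotic kinase gene Cdk1 2.74-fold lower.

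**Figure D3:**
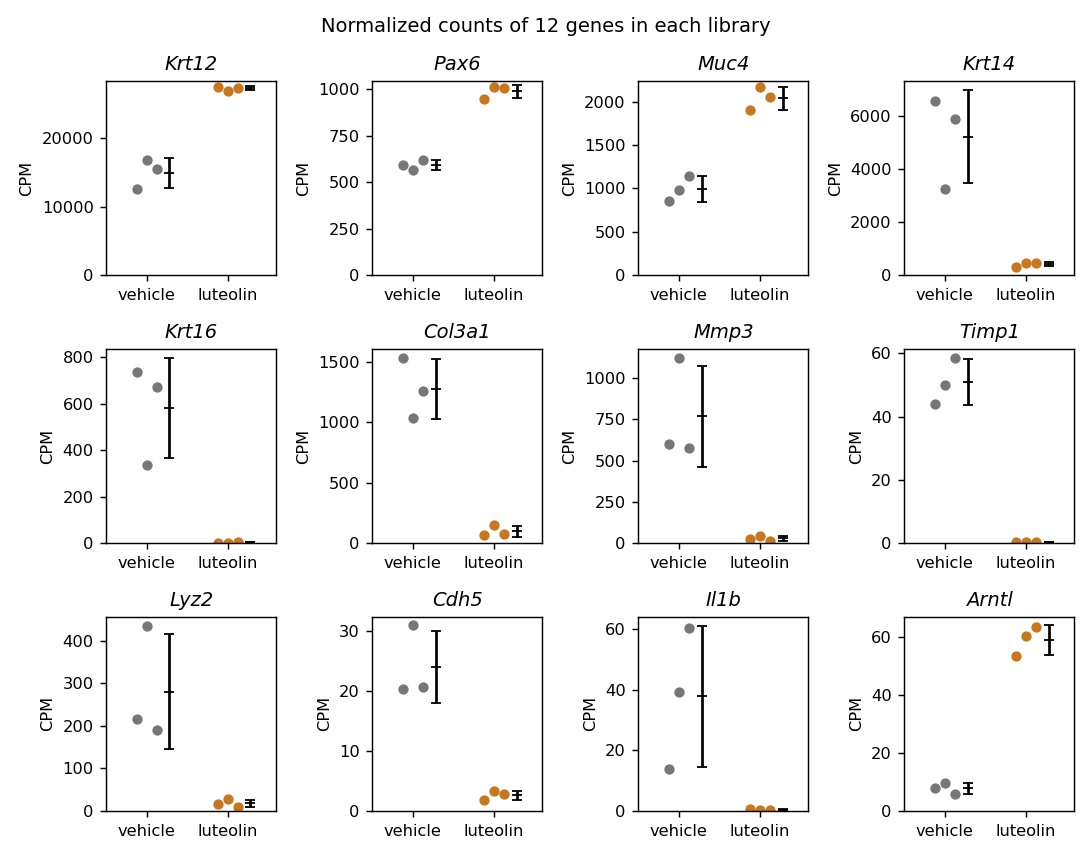
CPM of 12 genes in each vehicle and luteolin library (points, linear axes from 0), with the mean and SD of each group (n = 3) as a black bar beside them. Krt12, Pax6, Muc4 and Arntl were higher and the other 8 genes lower in all 3 luteolin libraries, and vehicle 2 had the lowest vehicle level of Krt14 (3223 CPM).

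Most cholesterol synthesis genes rose, and genes of fatty acid oxidation went both ways. Of 10 cholesterol synthesis genes 7 rose, or 8 adjusted over the list alone, and Idi1 and Mvd fell (median 0.49, camera adjusted p = 0.0215, and adjusted p = 0.639 with an estimated correlation). Insig1, a regulator of sterol sensing, was 2.02-fold higher, the transcription factor gene Srebf2 1.65-fold and Lss, lanosterol synthase, 1.41-fold. Without luteolin 1 or luteolin 3 the call of Idi1 ended (log2 fold changes -0.33 and -0.32) and 1 member was lower. Of 10 genes of fatty acid oxidation and PPAR targets 4 rose and 4 fell, or 5 adjusted over the list alone (median -0.16, camera adjusted p = 0.948). The oxidation genes Acadm and Cpt1a were 1.94-fold and 1.54-fold higher.

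Most oxidative phosphorylation genes fell by small amounts, and the call of the list ended after a correction for gene length. Of 15 oxidative phosphorylation genes 11 were lower (median -0.28, camera adjusted p = 0.00968, and adjusted p = 0.639 with an estimated correlation), with Ndufa4 1.94-fold, Uqcrq 1.57-fold, Atp5o 1.28-fold and Cox7b 1.24-fold lower. Of 16 ribosomal protein genes 5 were lower, or 1 adjusted over the list alone (median -0.13, camera adjusted p = 0.0942), with Rpl18, Rpl3, Rplp1 and Rps3 between 1.15-fold and 1.24-fold lower. Short genes were lower with luteolin: the median log2 fold change was -0.22 in the shortest of 10 length classes and 0.19 in the longest. After a per-library correction for length 4 oxidative phosphorylation genes were lower and 3 higher, with a median of -0.04 and a camera adjusted p of 0.472 (over the alternatives 0.00354 to 0.639), and 0 ribosomal genes were lower and 2 higher. The count of lower ribosomal genes was 11 with upper quartile factors, 12 with library sizes only, 2 without vehicle 1 and 1 without vehicle 3, luteolin 1 or luteolin 2, and the list passed with upper quartile factors, with library sizes only, and without vehicle 2 or luteolin 3 (camera adjusted p = 0.0207, 0.0195, 0.0418 and 0.0369, over the alternatives 0.0195 to 0.824). After the length correction none of the 4 named ribosomal genes, nor Atp5o and Cox7b, passed.

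The lists of stress pathways did not pass camera with all 6 libraries. Of 12 NRF2 antioxidant targets 8 fell, or 9 adjusted over the list alone, and 2 rose (median -0.40, camera adjusted p = 0.0663). The heme oxygenase gene Hmox1 was 7.23-fold lower, Me1 1.98-fold and Prdx1 1.39-fold, while Osgin1 was 2.01-fold higher. The list passed without vehicle 2 (camera adjusted p = 0.0282) and without luteolin 3 (0.0481), over the camera alternatives 0.0282 to 0.639. Of 3 tested aryl hydrocarbon receptor targets, Cyp1b1 (log2 fold change -1.54) and Ahrr (-1.17) fell, and 1 more rose adjusted over the list alone (camera adjusted p = 0.528). The call of Ahrr was lost without any 1 library except vehicle 3 (edgeR adjusted p 0.0636 to 0.112), without which 1 target was higher. Of 10 unfolded protein response genes 5 fell (camera adjusted p = 0.154), with Asns, asparagine synthetase, 7.16-fold, Sdf2l1 2.70-fold, the chaperone gene Hspa5 1.44-fold and Herpud1 1.29-fold lower, and without luteolin 1 a further 1 was higher. Of 12 p53 and apoptosis genes 4 fell and 2 rose (camera adjusted p = 0.491): Bax and Fas, which promote cell death, went from 29.7 to 14.9 and from 4.81 to 2.09 CPM, and Bcl2, which opposes it, and the cell cycle inhibitor Cdkn1a rose by 0.73 and 0.59 on the log2 scale. Of 13 immediate early and heat shock genes 3 rose and 5 fell, with a median of 0.05, a mean of -0.69 and an upward test (camera adjusted p = 0.980), so that the mean differed in sign; the median was -0.04 with upper quartile factors, -0.06 with library sizes only and -0.02 without vehicle 1. Nr4a1 (log2 fold change -5.30, without vehicle 2 -4.63) and Hsph1 (-0.89) fell, and Hspa1b and Dnajb1 were 1.65-fold and 1.31-fold higher. The number of lower members was 3 without vehicle 2, vehicle 3 or luteolin 3 and 2 without luteolin 2.

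Circadian clock genes moved in both directions. Of 14, 5 rose and 3 fell (camera adjusted p = 0.452). Arntl (gene ID 11865), which encodes the clock activator BMAL1, went from 7.77 ± 1.88 to 59.0 ± 5.08 CPM (SD, n = 3), a log2 fold change of 2.92 (SE 0.167, edgeR adjusted p = 4.54e-05). Npas2, Hlf and Clock were 2.58-fold, 2.27-fold and 1.51-fold higher and Cry1 1.61-fold, while Dbp (log2 fold change -1.12), Ciart (-1.27) and Per2 (-0.85) fell. The number of lower members was 1 without vehicle 3, luteolin 2 or luteolin 3 and 6 without luteolin 1. The call of Per2 ended without vehicle 2, vehicle 3, luteolin 2 or luteolin 3 (log2 fold changes -0.82 to -0.70) and that of Ciart without vehicle 1, vehicle 3, luteolin 2 or luteolin 3 (-1.33 to -0.93), and Ciart had -1.94 without luteolin 1.

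The lists of nerve, photoreceptor and pigment cell markers did not pass. Of 8 Schwann cell and nerve genes 5 fell and 2 rose (camera adjusted p = 0.613): the sodium channel gene Scn7a was 2.66-fold lower, and Mbp and L1cam were 2.89-fold and 1.40-fold higher. The number of lower members was 2 without luteolin 1 and 3 without vehicle 1, vehicle 2, luteolin 2 or luteolin 3. None of the 3 tested photoreceptor genes passed (camera adjusted p = 0.760), with Sag at 0.547 ± 0.320 and 1.12 ± 0.0767 CPM and Rom1 at 2.43 ± 0.865 and 2.13 ± 0.245 CPM (SD, n = 3, vehicle first), and Sag passed without vehicle 2 (log2 fold change 1.53, edgeR adjusted p = 0.0205, over the alternatives 0.0205 to 0.184). None of the 3 tested pigment cell genes passed (camera adjusted p = 0.697), with Tyrp1 at 3.81 ± 3.44 and 1.21 ± 1.03 CPM and Dct at 9.76 ± 7.75 and 4.83 ± 0.931 CPM (SD, n = 3), and 4 of 5 were lower without vehicle 3 and 1 of 5 without luteolin 2. The lens and red blood cell lists each had 1 tested gene: Bfsp1 fell by 1.02 on the log2 scale, and Alas2 was 1.88-fold higher.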

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

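The length correction and the muscle covariate were chosen after seeing the data. The number of genes changed (8157) ran from 7371 with the muscle covariate to 8304 with no filter, and from 6795 to 8493 when 1 library was left out, always within 1.5 times. DESeq2 gave 7972 genes, of which 7650 were among the 8157. With the replicate number as a block 7934 genes passed (7693 shared) and 16 lists. Same-numbered libraries did not deviate together (correlations -0.15, 0.03 and 0.01) and 1 of 6 libraries correlated best with its own number. These values gave no sign of pairing by number, but so few libraries cannot exclude it. The block also gave 8 lower and 1 higher keratocyte genes, with a camera adjusted p of 0.0311 (over the alternatives 0.0311 to 0.827). With a correlation estimated from the data 0 lists changed, 0 higher and 0 lower, where the test allows for the correlation that the libraries show within a list. Correlation within lists does not account for all of this loss. The matrix metalloproteinase and neutrophil lists had estimated correlations of -0.048 and 0.0069, below the preset 0.01. Their calls ended as well (camera adjusted p = 0.410 and 0.495 with an estimated correlation). Other settings gave 14 to 18 lists, fry 21. Of 138 genes chosen by the naming rule 120 kept their direction and side of the threshold under every alternative checked gene by gene. Limma-trend on log2 FPKM was used only for the number of genes changed, so it is in neither this check nor the ranges over the alternatives. Among the 18 others were Ahrr, Atp5o, Ckm, Col1a2, Cox7b, Dct, Krt10, Myh1, Rom1, Rpl18, Rpl3, Rplp1, Rps3, Sag, Tfap2b, Traf6 and Tyrp1. In the following cases the direction of a list test or of a gene turned, and the cause was not tested unless stated. With the length correction the ribosomal list had a median of 0.073, Rplp1 0.0082 and the fatty acid list a median of -0.10. With the muscle covariate the skeletal muscle list had 0.11, because the covariate is that list's own mean, the immediate early list 0.017 and Rom1 0.014. With no filter the photoreceptor list had -1.22, from 8 tested genes in place of 3, and the fatty acid list -0.15. The test of fry was upward for the Schwann cell and nerve list, whose median was -1.11. Leaving out 1 library turned the test of pigment cells, of fatty acids and Rom1 (without vehicle 2) and of the immediate early list (without vehicle 1 or luteolin 1); values then ran from -1.88 to -0.25 for pigment cells, -0.19 to -0.13 for fatty acids, -0.44 to 0.091 for Rom1 and -0.023 to 0.149 for the immediate early list. With no filter the medians of wound keratins (-3.02) and of conjunctiva (-0.27) moved by over 1.5 times. An alternative for a table holding only FPKM or TPM was not run, because counts were present. Depth limits genes with few luteolin counts to bounds and intervals.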

Other observations

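Families of genes that share a symbol stem, grouped after seeing the data, added gene groups that the fixed lists did not hold. Of 128 families with at least 12 tested members 26 passed camera with the preset correlation, 9 upward and 17 downward, and 0 with an estimated correlation (lowest adjusted p = 0.596). Receptor and ligand families of immune cells were among those that fell: 13 of 16 Ccl chemokines fell and 0 rose (median -4.37), 17 of 19 C-type lectins (Clec) fell and 2 rose (-3.57), 31 of 46 interleukin and interleukin receptor genes (Il) fell and 4 rose (-0.95), and 11 of 17 TNF receptor genes (Tnfrsf) fell and 0 rose (-1.24), where 1 rose without vehicle 2 and 2 without vehicle 3. Among genes of matrix and adhesion 12 of 14 Adamts proteases fell (-2.09), although Adamts18 was among the 10 largest increases by the naming rule, and 9 of 12 integrin alpha genes fell (-1.27). Some of these genes also stand in the fixed lists, so the counts are not independent of them.

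Among the families that passed upward, the changes were small in the following. Of 351 zinc-finger genes (Zfp) 143 rose and 21 fell (median 0.25), of 41 Zbtb transcription factors 26 rose and 2 fell (0.38), of 17 histone demethylases (Kdm) 13 rose and 1 fell (0.36), of 35 Vps genes of vesicle sorting 21 rose and 1 fell (0.26), and of 16 peroxisome genes (Pex) 10 rose and 0 fell (0.30). With library sizes only the medians stayed above 0 (Zfp 0.14, Zbtb 0.27, Kdm 0.24, Vps 0.15, Pex 0.19), and 99 Zfp, 13 Vps and 2 Pex genes rose. After the length correction the medians were 0.22 for Zfp, 0.30 for Zbtb, 0.29 for Kdm, 0.17 for Vps and 0.32 for Pex. Then 131 Zfp, 25 Zbtb, 10 Kdm, 17 Vps and 10 Pex genes rose. Each of these families still passed camera with the preset correlation (adjusted p 0.00172 to 0.0274). The number of Pex genes that rose was 4 without vehicle 1 and 5 without luteolin 2 or luteolin 3. Nucleoporins (Nup) went the other way, with 12 of 20 lower and 1 higher (-0.44).

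Tests of epithelial share, of conjunctiva, of collection time and of the 2 families taken singly were chosen after the result was seen, and the length correction and muscle covariate were added after seeing the data. The 6 libraries allow 10 splits, too few for a share under 0.05: the real split gave 8157 genes and the highest other 0 by edgeR (at most 400 at an unadjusted p under 0.05), with 1 split as large, and 15 lists against 16 for the highest other, with 4 splits as large. Every other split mixes both treatments within its groups, which widens their spread and leaves part of the treatment contrast between them. Neither count is therefore a rate expected by chance.

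Zinc-finger and mitochondrial ribosome genes moved apart, and a gene length trend is a candidate explanation. The slope of log2 CPM per doubling of length was between -0.07 and -0.03 in the vehicle libraries and between 0.03 and 0.07 in the luteolin libraries, and Zfp genes (median length 3377) are longer than Mrpl and Mrps genes (757). After the length correction the Zfp median was 0.22 (SE 0.0206, before 0.25, SE 0.0255) with a camera adjusted p of 0.00172 (adjusted p = 0.595 with an estimated correlation, before 0.596). The SEs in this paragraph come from resampling the genes of a family as if independent, and they leave out the spread between libraries. The Zfp median kept most of its size, which argues against length as the whole cause for that family in these libraries. For the 78 mitochondrial ribosome genes the median went from -0.37 (SE 0.0344) to -0.16 (SE 0.0358), with a camera p of 0.00377 as 1 group, and the gap between the families from 0.62 (SE 0.0422) to 0.38 (SE 0.0415). Both lay within 2 standard errors of the limits set for them, so that length as the whole cause and treatment cannot be told apart for these genes, and the calls of Mrpl and Mrps as separate families ended (camera adjusted p = 0.0610 and 0.175, and adjusted p = 0.902 and 0.883 with an estimated correlation) because their medians shrank.

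Mean levels of the macrophage, neutrophil and vessel lists were lower in each luteolin library than in each vehicle library. Muscle-bearing tissue from outside the cornea would have to end the change with the muscle covariate, but the median of the 29 members was -2.77 (SE 0.196, before -2.89), which says nothing of other tissue. Of the 5 tested conjunctival genes the keratins Krt4 (log2 fold change -1.28), Krt13 (-0.78) and Krt19 (-0.66) fell as well, and the other 2 did not pass. The 5 had a median of -0.66 (SE 0.417) and a mean of -0.44. SEs of medians in this paragraph come from resampling genes as if independent, and they leave out the spread between libraries. Less conjunctiva on the luteolin corneas and treatment cannot be told apart, because 3 of the 5 stood over 50 CPM with luteolin, a level that could hide a lost share. Only 2 stood under it, where the test needed 3. A larger share of epithelium in the luteolin corneas would lower every other cell type alike, but the mean log2 CPM of the 29 members fell further than that of the 19 keratocyte and corneal endothelium genes, by -2.23 (SE over the libraries 0.454, -2.58 to -1.95 with 1 library left out; exact permutation test over the 6 libraries, p = 0.1, the smallest it can give). A larger share of epithelium could still account for part of the change. Less conjunctiva, a lower content of immune and vessel cells in the cornea, or lower expression in them stay open as well, and counts of stained cells or single-cell sequencing of such corneas would test them.

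Clock genes moved in opposite directions, with Arntl up and Dbp down. The length trend was too small to account for it, with median log2 fold changes of -0.22 in the shortest and 0.19 in the longest of 10 length classes. The correction could therefore remove little: after it Arntl had a log2 fold change of 2.92 (SE 0.167, edgeR adjusted p = 4.77e-05) and Dbp -0.99 (SE 0.228, edgeR adjusted p = 0.00805). A different time of day at collection is a possible explanation, and of 7 output and repressor genes 2 passed in the direction opposite to Arntl (Dbp and Ciart), 1 with it (Hlf), and 4 did not pass, while Ciart lost its call without vehicle 1, vehicle 3, luteolin 2 or luteolin 3 (log2 fold changes -1.33 to -0.93). Outside these 7 genes Per2 also fell, a call that ended without vehicle 2, vehicle 3, luteolin 2 or luteolin 3, while Npas2, Clock and Cry1 rose with Arntl. Time and treatment cannot be told apart here, since the labels give no collection time.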
